A study of Strongylocentrotus intermedius with 6 samples.

How the data were processed

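RNA-seq libraries of sea urchin (Strongylocentrotus intermedius) coelomocytes were labelled with the times ZT0 or ZT12 and the light regime LD, with 3 libraries per time. Per the labels' protocols, total RNA was extracted with TRIzol, its purity and integrity were checked by spectrophotometer and Bioanalyzer, libraries were prepared with a VAHTS universal RNA-seq kit, and sequencing was done by OE Biotech. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used. Their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Without a known strand setting, reads of a gene and of a model overlapping it on the other strand cannot be told apart, and HTSeq's handling of reads that match several genes is likewise unknown. Values of members of multigene families are therefore uncertain where near-identical copies could share reads.

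The authors deposited a table of whole-number counts per gene for all 6 libraries, not normalized, with gene symbols, descriptions and pathway terms beside the identifiers. The authors also deposited FPKM values, 1 table per library. In a check over 68340 values with enough reads, 100% of the deposited FPKM values equalled the counts divided by the library total and by one length per gene, within 0.1%. The 2 kinds of deposited file therefore hold the same measurement, and the counts were used for the main results. Symbols and descriptions are the authors' and come from similarity to genes of other species. No genome sequence or annotation was used here, so positions of genes are not analysed here.

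Libraries were grouped by the time in the labels. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total count 15), library sizes were scaled by TMM, and the quasi-likelihood fit (glmQLFit with legacy = FALSE, glmQLFTest) compared ZT12 minus ZT0. P-values were adjusted by Benjamini-Hochberg over the 18456 genes tested, with a false discovery rate of 0.05 as the threshold. A standard error is the absolute log2 fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over the 3 libraries of a time, and fold changes are edgeR's fitted values. All adjusted p-values of single genes in the text are from this edgeR test unless another tool is named. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so single values were compared through the edgeR model.

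The design, the tests, the alternatives, the rule for naming genes and the 40 gene lists were set before the data were examined. Lists covered the clock and light sensing, immune receptors and effectors, stress, metabolism, gene expression machinery, and markers of cell types or tissues that coelomic fluid could hold. Lists were patterns on symbols and descriptions. After the gene names were seen, 22 lists had members with an unrelated name removed, on names alone, and the result without these removals was added as an alternative. In total 39 lists had at least 3 tested members and 1, for a coelomocyte-specific immune protein family, had no tested member. Each list was tested with limma 3.58.1 camera on log-CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, stood beside it. Counts of changed members were taken over all genes tested and adjusted over the list alone.

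Genes were named by 4 rules. These took up to 10 called genes per direction with the largest fold change, a symbol or description, libraries that separate by time and at least 1 CPM in the higher group; up to 4 members of each list with the smallest p; every tested cryptochrome, photolyase, timeless, clock, BMAL, Rev-erb, ROR or PAR bZIP gene of the clock list; and the 5 most abundant genes. Some list members were left out for length. Any gene outside the rules is said to be so where it is named.

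The steps were tested on simulated counts drawn from these libraries' means and sizes, with 200 genes changed by known folds, of which those that passed the filter are counted here. In this simulated ZT12 against ZT0 comparison, over 17748 genes, edgeR recovered 0% of the 2-fold changes, 29.2% of the 4-fold, 66% of the 8-fold and 85.7% of the 16-fold changes, and 14 of its 102 calls were false (13.7%). DESeq2 1.42.0, over 18456 genes, made 182 calls, of which 70 were false (38.5%), and limma-voom, over 17748 genes, made 72, of which 4 were false (5.6%). With legacy = TRUE, edgeR made 81 calls over 17748 genes, of which 4 were false (4.9%). The list test found the list of simulated shifted genes and no other list, with the preset and with the estimated correlation. Simulated genes were drawn independently of each other. The simulation therefore could not show how often lists pass falsely when their members move together. Totals of 20229918 to 24368884 counts per library put 3 counts, the limit that a count of 0 allows, at 0.123 to 0.148 CPM, which covers counting error only.

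Alternatives were other scalings (DESeq2 size factors, upper quartile, plain library sizes, leaving out the 20 most abundant genes), other tools (DESeq2, limma-voom, edgeR with legacy = TRUE or robust = TRUE), other filters (none, or at least 1 CPM in 3 libraries), a log2 fold threshold of 1, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. DESeq2 was run with a target false discovery rate of 0.05 and its default filtering. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.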

Results

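RNA was sequenced from coelomocytes, the immune cells of the coelomic fluid, of the sea urchin Strongylocentrotus intermedius. Animals were under LD, by convention a cycle of light and dark, and libraries were labelled ZT0 or ZT12 (zeitgeber time, by convention hours counted from lights-on), with 3 libraries at each time. The hours of light are not given in the sources used here. The series title names photoperiod and Cryptochrome1 in immunity, and the comparison asks which transcripts differed between these 2 times of day. The count table held 30559 gene models, 22969 coding and 7590 long noncoding (lncRNA), and 15723 carried a gene symbol. Total counts were 24368884, 20229918 and 20325433 in ZT12 libraries 1, 2 and 3, and 21610460, 22478512 and 21909627 in ZT0 libraries 1, 2 and 3. Counts were found for 23487 to 24677 genes per library. The Spearman correlation between libraries, taken across genes, which are not independent replicates, was 0.905 to 0.926 within a time and 0.893 to 0.916 between times. No pair of libraries held identical values. The labels do not say whether the libraries came from separate animals or from pools, so p-values measure only the spread between these samples. That spread may be partly technical. Against a purely technical spread stand 111 genes, described below. They were under 0.1 CPM in some libraries of a time and above 1 CPM in others of that time, with at least 10 CPM in the highest library.

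The most abundant transcripts were those of a cytoskeletal actin, CYIA (ZJQ009269), at 21400 ± 1970 CPM at ZT12 and 27500 ± 5220 CPM at ZT0 (SD, n = 3). Next came TIMP3 (ZJQ003888, a metalloproteinase inhibitor), a soma ferritin gene (ZJQ012741, iron storage), the translation elongation factor gene tef2 (ZJQ013148) and Svep1 (ZJQ009371). None of these 5 genes passed the test between times, with edgeR log2 fold changes (ZT12 minus ZT0) of -0.36 for CYIA, -0.45 for TIMP3, -0.14 for the ferritin gene and tef2, and -0.23 for Svep1. The 20 most abundant genes took 11.2 to 12.8% of the counts of a library.

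Several genes of the skeleton-forming programme, though not all of those tested, had far lower transcript levels at ZT12 than at ZT0. The spicule matrix genes SM50 (ZJQ010321), PM27 (ZJQ010317), SM30A (ZJQ010417) and SM30 (ZJQ010416), whose proteins are embedded in the calcite skeleton, were 19.1-, 27.5-, 17.1- and 53.6-fold lower. A NOD-like receptor gene annotated nlrp1 (ZJQ022614), of a family of cytosolic pathogen sensors, went the other way, from 0.302 ± 0.401 CPM at ZT0 to 42 ± 28.4 CPM at ZT12 (SD, n = 3). Across the transcriptome few genes passed the test, and most of these were lower at ZT12. Of 18456 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 24 changed, 3 higher and 21 lower at ZT12, and 1349 had an unadjusted p under 0.05 (634 higher, 715 lower). The smallest absolute log2 fold change among the 24 was 3.64, 14 had a symbol or description and 3 were lncRNA models. The count depended on the tool and on the genes tested: DESeq2 over 28940 genes called 264 (133 higher, 131 lower), including all 24, edgeR with legacy = TRUE called 10 and limma-voom called 0 (1078 at an unadjusted p under 0.05). Limma-trend on log2(FPKM + 1) called 21 (4 higher, 17 lower) among the 18456 genes and 1 among the 29286 with a total above 0. With fewer libraries calls were lost more than fold changes: edgeR called 0 genes without ZT12 library 1 or 3 (1398 and 1502 at an unadjusted p under 0.05), where SM50 was still at -4.3 and -4.12 on the log2 scale (adjusted p = 0.0602 and 0.0617), and none of the 3 higher genes was called without any single ZT0 library, whereas 12 higher and 12 lower were called without ZT12 library 2.

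**Figure D1:**
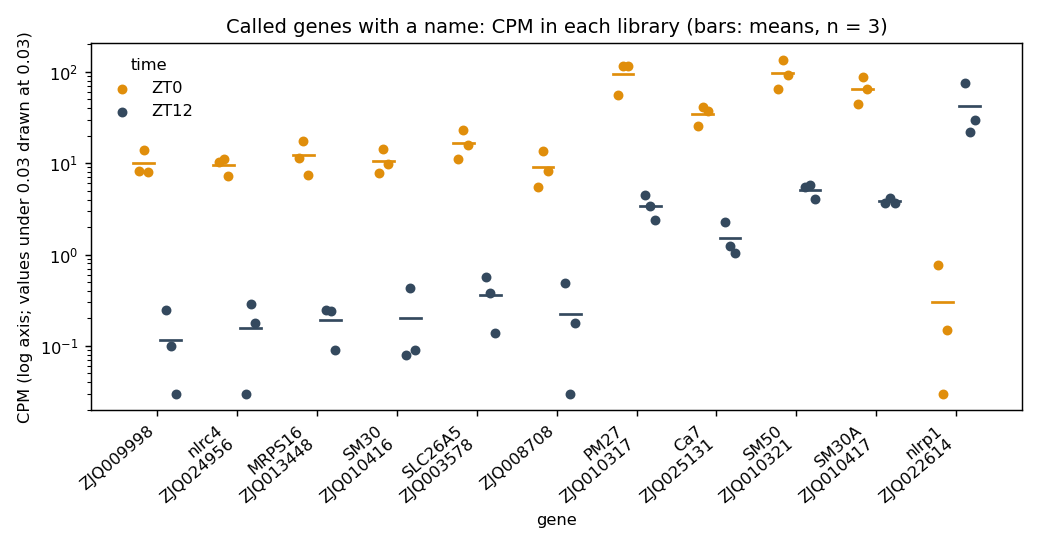
CPM (log axis, values under 0.03 drawn at 0.03) of the 11 named genes with the largest called changes, one point per library and bars at the mean of 3 libraries. In each gene the ZT0 points (orange) and ZT12 points (dark blue) do not overlap, which the naming rule required, and nlrp1 alone among these 11 is higher at ZT12.

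Among the biomineral markers, 6 of the 11 tested members fell at ZT12 and 5 did not pass the test over all genes. Adjusted over the list alone, 8 were lower and 1 was higher. SM50 had 97.1 ± 35.3 CPM at ZT0 and 5.07 ± 0.921 CPM at ZT12 (SD, n = 3; log2 fold change -4.26, SE 0.35, edgeR adjusted p = 0.00587). PM27 had 95.1 ± 34.5 CPM at ZT0 and 3.43 ± 1.06 CPM at ZT12 (-4.78, SE 0.4, adjusted p = 0.0059). SM30 and SM30A had log2 fold changes of -5.75 and -4.09, both with an adjusted p of 0.00587. The other called members were 2 genes for mesenchyme-specific cell surface glycoproteins, a family on the surface of skeleton-forming mesenchyme cells: ZJQ008708 (-5.24, SE 0.75, adjusted p = 0.0396) and ZJQ008711 (-4.04, adjusted p = 0.0396), the latter chosen after its values were seen. Over the list the median log2 fold change was -4.04, with 8 members below and 3 above 0. The list passed camera (adjusted p = 7.49e-11; adjusted p = 0.544 with an estimated correlation) and fry (adjusted p = 0.0272). Its members made up 0.0575% of counts at ZT0 and 0.013% at ZT12. SM30 and SM30A, or the glycoprotein genes, could share reads, which was not checked here, so their separate values are uncertain.

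Other called genes outside that list included Ca7 (ZJQ025131), a carbonic anhydrase, an enzyme class that interconverts carbon dioxide and bicarbonate. It had 34.7 ± 8.41 CPM at ZT0 and 1.53 ± 0.669 CPM at ZT12 (SD, n = 3; log2 fold change -4.48, SE 0.39, edgeR adjusted p = 0.00668). SLC26A5 (ZJQ003578), annotated as prestin, of a family of anion transporters, fell by 5.48 on the log2 scale (SE 0.55, adjusted p = 0.00807). Further called genes lower at ZT12 were ZJQ009998 (C-type lectin lectoxin-Lio1, -6.35, SE 0.69, adjusted p = 0.00587) and, chosen after their values were seen, ZJQ010319 (snaclec jerdonibitin, -4.06, adjusted p = 0.00587, 134 ± 47.9 CPM at ZT0) and Reg2 (ZJQ010301, lithostathine-2, -3.64, adjusted p = 0.0366). MRPS16 (ZJQ013448), a mitochondrial ribosomal protein gene, had 12.1 ± 5.07 CPM at ZT0 and 0.191 ± 0.0868 CPM at ZT12 (log2 fold change -5.94, SE 0.58, adjusted p = 0.00587). In ZT0 libraries 1, 2 and 3, SM50 had 64.17, 134.39 and 92.84 CPM and ZJQ010319 had 88.96, 184.15 and 127.44 CPM. Ca7, SLC26A5 and Reg2 were also lowest in library 1 and highest in library 2, while ZJQ009998 and MRPS16 were lowest in library 3. The genes outside the list are therefore not shown to change apart from it. The 14 named called genes kept their direction but were not called by edgeR without ZT12 library 1 (adjusted p from 0.0602 to 0.188) or 3 (0.0617 to 0.221). Ca7, for example, was at -4.91 and -4.28. ZJQ008711 lost its call whichever library was left out (edgeR adjusted p from 0.0593 to 0.188). ZJQ008708 and Reg2 kept theirs only without ZT0 library 1 (0.045 and 0.0256), and nlrp1 only without ZT12 library 2 (0.0338). ZJQ009998 (0.0557) and SLC26A5 (0.0533) also lost theirs without ZT12 library 2.

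No core clock gene passed edgeR's test, and the largest differences were in BMAL1, the partner of CLOCK in the activating arm of the animal clock. A daily change with like levels at ZT0 and ZT12 cannot be seen with these 2 times. Smaller changes would also mostly be missed, since edgeR recovered 0% of the 2-fold and 29.2% of the 4-fold changes in the simulated comparison. Bmal1 (ZJQ011976) had 17.5 ± 8.1 CPM at ZT12 and 4.56 ± 3.05 CPM at ZT0 (SD, n = 3; log2 fold change 1.92, SE 0.54, edgeR adjusted p = 0.444). An lncRNA model annotated BMAL1 (lncRna04157) had 15.4 ± 10.8 and 3.72 ± 0.588 CPM (2.04, SE 0.56, adjusted p = 0.42), and may count reads of the same locus. DESeq2 called the lncRNA model (adjusted p = 0.027) and not Bmal1 (adjusted p = 0.0518). In CLOCK (ZJQ017717) the log2 fold change was 0.83 (SE 0.33, adjusted p = 0.648), and in 1 of 3 Rev-erb-type Nr1d2 genes (ZJQ018676) it was 0.86 (adjusted p = 0.654). In these 4 models the ZT12 libraries all lay above the ZT0 libraries, and in 1 HLF gene (ZJQ000791) all lay below, a separation that chance gives for 10% of genes, while the other 12 of the 17 named clock genes overlapped. CRY1 (ZJQ010072), a cryptochrome of the type that the series title names, had 27.6 ± 14.3 CPM at ZT12 and 35.9 ± 7.94 CPM at ZT0 (log2 fold change -0.38, SE 0.39, adjusted p = 0.884), a difference within the spread between libraries. The other cryptochrome genes also did not pass: cry (ZJQ010692) at 0.63, cry-dash (ZJQ000319) at 0.96, Cry2 (ZJQ009245) at -0.5, and Cry2 (ZJQ009229) at -0.11, which was 0.05 with plain library sizes. The sign for cry-dash, both Cry2 genes and PHR turned when single libraries were left out. The remaining clock genes lay between -0.3 and 0.54, namely HLF (ZJQ000791) at -0.3, Nr1d2 (ZJQ019208) at -0.29, TEF (ZJQ001187) at -0.16, RORA (ZJQ003336) at -0.15, the photolyase gene PHR (ZJQ014263) at 0.08, HLF (ZJQ017941) at 0.25, Nr1d2 (ZJQ000820) at 0.4 and Timeless (ZJQ002987) at 0.54. Of the 20 tested members of the clock list 0 were called by edgeR over all genes or adjusted over the list alone, where the lowest adjusted p was 0.0799, and 4 had an unadjusted p under 0.05. The list did not pass camera (adjusted p = 0.0632; adjusted p = 0.544 with an estimated correlation) or fry in one direction (adjusted p = 0.122). It passed fry for change in either direction (adjusted p = 0.0343), which 9 of the 39 lists passed and which does not compare a list with other genes.

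**Figure D2:**
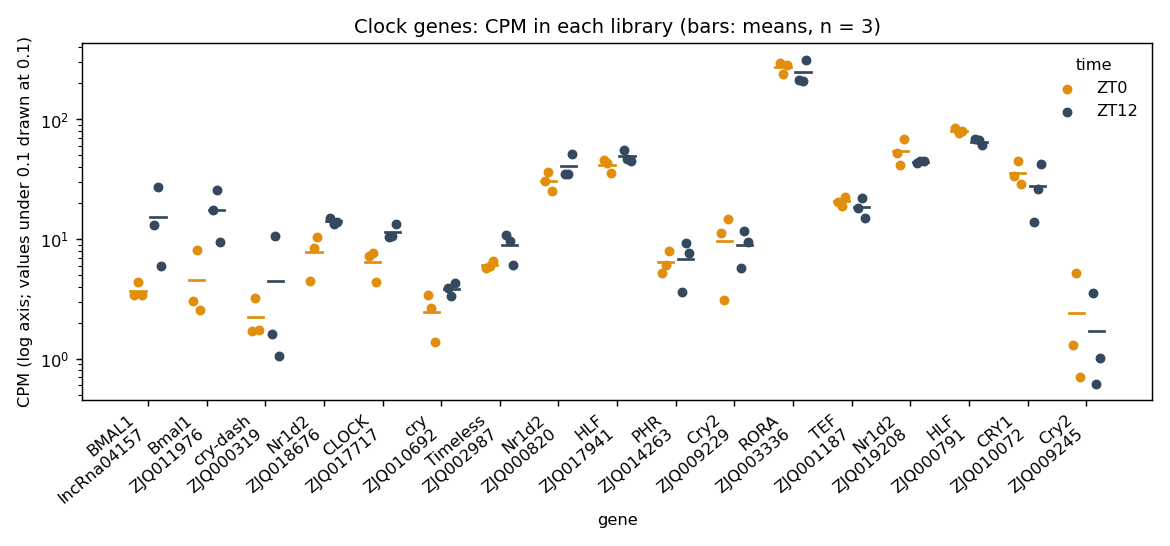
CPM (log axis) of the 17 named clock genes in each library, with bars at the mean of 3 libraries per time (ZT0 orange, ZT12 dark blue). The BMAL1 models lie higher at ZT12 without overlap, while the points of CRY1 overlap between times.

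Few single immune receptor genes passed edgeR's test over all genes. Of 139 tested NOD-like receptor genes, nlrp1 (ZJQ022614; log2 fold change 7.17, SE 0.84, edgeR adjusted p = 0.0145) rose and an nlrc4 gene (ZJQ024956; -5.95, SE 0.66, adjusted p = 0.00587) fell, and 137 did not pass, with 33 of the 139 at an unadjusted p under 0.05. Adjusted over the list alone, 5 were higher and 3 lower, among them nlrc5 (ZJQ002418, 2.6) and a further nlrc4 gene (ZJQ012443, -3.1). The list did not pass camera (adjusted p = 0.228), with 85 members above and 54 below 0, while fry's test for change in either direction gave an adjusted p of 5e-05. Of 72 tested lectin genes 1 was lower, ZJQ009998 above, and 71 did not pass; adjusted over the list alone 1 was higher and 2 were lower. These included an echinoidin gene (ZJQ008251, a lectin of coelomic fluid), with 0.55 ± 0.326 CPM at ZT12 and 11.6 ± 5.94 CPM at ZT0 (SD, n = 3; edgeR adjusted p = 0.0645 over all genes, 0.00362 over the list; DESeq2 4.79e-10 over all genes), and CLEC6A (ZJQ002468), with 46.6 ± 28.4 and 0.657 ± 1.1 CPM (adjusted p = 0.109 over all genes, 0.00523 over the list). The lectin list did not pass camera (adjusted p = 0.842) but passed fry in either direction (adjusted p = 0.000186), and 10 members had an unadjusted p under 0.05. Copies within these families could share reads, which was not checked here, so single values are uncertain.

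The 65 tested Toll-like receptor genes, which code for membrane receptors of microbial products and form a large family in sea urchins, stood higher at ZT12 as a list, by a small amount. Their median log2 fold change was 0.30, with 47 members above and 18 below 0, and the list passed camera (adjusted p = 6.92e-05; adjusted p = 0.544 with an estimated correlation). No member passed edgeR's test, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. Examples were TLR4 genes with 0.795 ± 0.411 CPM at ZT12 and 0.173 ± 0.0738 CPM at ZT0 (ZJQ022154; SD, n = 3), and 32.4 ± 13.2 and 15.3 ± 2.65 CPM (ZJQ009342). The median member lay lower in ZT12 library 1 (0.04 log2 units from its gene's mean) than in ZT0 library 1 (0.08), and without ZT0 library 2 the list no longer passed (adjusted p = 0.0769). In the complement and thioester list, 0 of 16 members were called by edgeR and the list did not pass camera (adjusted p = 0.0632; 0.00738 without ZT12 library 2), though it passed fry in either direction (adjusted p = 0.0423). C3 (ZJQ009111), the central complement component, had 730 ± 537 CPM at ZT12 and 154 ± 87.7 CPM at ZT0 (log2 fold change 2.24, SE 0.69, edgeR adjusted p = 0.505, DESeq2 0.0355), with overlapping libraries. C1qtnf4 (ZJQ012846) had 25.8 ± 11.6 and 63.4 ± 10.8 CPM (adjusted p = 0.401). Other immune lists did not pass camera either: scavenger receptors (SRCR) and antiviral genes (adjusted p = 0.228 each), cytokines (0.625), antimicrobial effectors (0.842), phagocytosis and lysosome (0.774), and signalling from Toll-like receptors through NF-kB (0.942).

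Markers of the gut and of digestion stood higher at ZT12 as a list. Their median log2 fold change over 40 tested members was 1.60 (3.03-fold), with 33 members above and 7 below 0, and camera gave an adjusted p of 7.42e-07 (adjusted p = 0.801 with an estimated correlation). Over all genes 0 members were called by edgeR (15 at an unadjusted p under 0.05), and adjusted over the list alone 9 were higher. Among them were a lactase/phlorizin hydrolase gene, LCT (ZJQ000717), with 5.35 ± 1.88 CPM at ZT12 and 0.199 ± 0.344 CPM at ZT0 (SD, n = 3; edgeR adjusted p = 0.143 over all genes, 0.0167 over the list), and the sucrase-isomaltase gene SI (ZJQ014773), with 9.79 ± 8.19 and 0.398 ± 0.564 CPM (0.224 and 0.019). DESeq2 called both over all genes (adjusted p = 0.0089 for LCT and 0.00352 for SI). The libraries of a time differed in these markers: the median member lay 1.28, -0.25 and 1.4 log2 units from its gene's mean in ZT12 libraries 1, 2 and 3, and -1.1, -0.9 and 0.18 in ZT0 libraries 1, 2 and 3. ZT12 library 2 was thus below ZT0 library 3. Summed over members the list made up 0.398% of counts at ZT12 and 0.422% at ZT0, mostly from a trypsin-1 gene chosen after its values were seen (ZJQ009370), with 3330 ± 119 and 4000 ± 627 CPM (log2 fold change -0.26, edgeR adjusted p = 0.84). The list passed camera without any single library, with adjusted p from 3.74e-12 to 0.000968. These fits kept the preset correlation of 0.01, against 0.211 estimated for this list, so they do not test whether the preset is too low. At the preset value 7 of 10 splits of the libraries, the split by time included, passed at least 5 lists.

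**Figure D3:**
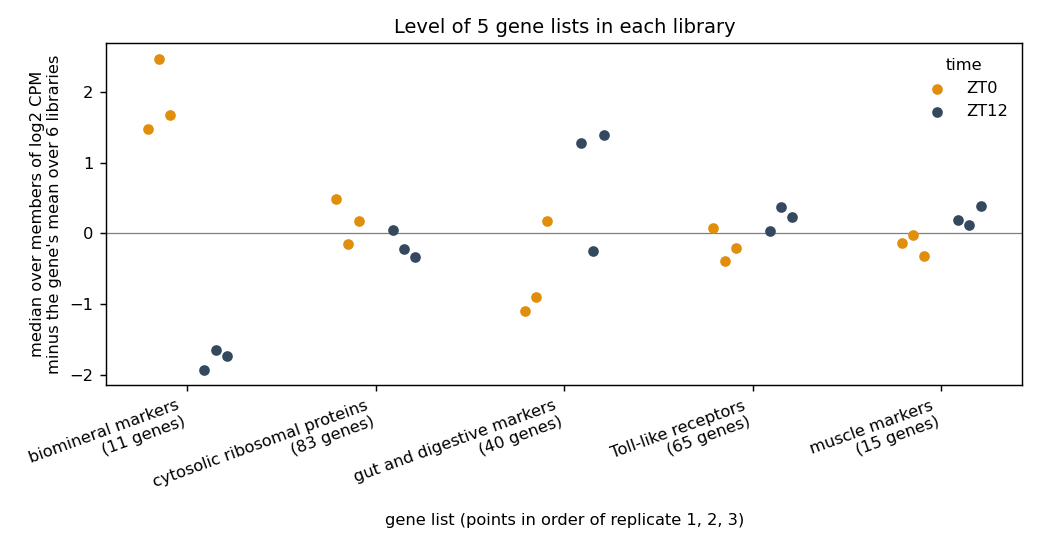
Level of the 5 lists that passed camera in each library, as the median over members of log2 CPM minus the gene's mean over 6 libraries (ZT0 orange, ZT12 dark blue, points in order of replicate). Biomineral and muscle markers separate the times in all libraries, whereas the times overlap for ribosomal proteins, Toll-like receptors and digestive markers, where ZT12 library 2 (-0.25) lies below ZT0 library 3 (0.18).

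Cytosolic ribosomal protein genes stood slightly lower at ZT12 as a list. Of 83 tested members 79 had a negative log2 fold change, with a median of -0.37 (1.29-fold lower), and they made up 8.71% of counts at ZT12 and 10.3% at ZT0. Camera gave an adjusted p of 1.97e-08, but the members moved together between libraries, and the adjusted p was 0.917 with an estimated correlation. The times overlapped, since the median member lay 0.05, -0.22 and -0.34 log2 units from its gene's mean in ZT12 libraries 1, 2 and 3 and 0.49, -0.15 and 0.18 in ZT0 libraries 1, 2 and 3, and without ZT0 library 1 the adjusted p was 0.0277. ZT12 library 1 and ZT0 libraries 1 and 3 all lay above the other libraries, so the list separated by that grouping and not by time. No member was called by edgeR (3 at an unadjusted p under 0.05). RPL26 (ZJQ007027) had 865 ± 67.8 CPM at ZT12 and 1260 ± 242 CPM at ZT0 (SD, n = 3; adjusted p = 0.625), and rpl36a (ZJQ010069) had 807 ± 114 and 1300 ± 418 CPM (adjusted p = 0.627). The 15 muscle markers had a median of 0.37 and passed camera narrowly (adjusted p = 0.0489; adjusted p = 0.544 with an estimated correlation), with 0 members called by edgeR, for example Ttn (ZJQ022598, titin) at a log2 fold change of 1.61 (adjusted p = 0.567) and RYR2 (ZJQ000331, a calcium channel) at 0.89 (adjusted p = 0.703). The muscle list no longer passed without ZT12 library 1 (0.0846) or 3 (0.209), or without ZT0 library 1 (0.072), 2 (0.0711) or 3 (0.139). Markers of other coelomocyte types did not pass camera, with adjusted p of 0.228 for red spherule cells (the pigmented type) and for ciliated cells and 0.927 for phagocytes, and neither did neural (0.172) or gonad markers (0.942). In total 34 of the 39 tested lists did not pass, with adjusted p from 0.0538 to 0.942.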

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

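Leaving out ZT12 libraries 1 and 3 together, the removal of the biomineral, gut and muscle members, and the lists before name removals were chosen only after the results were seen. Of the 68 named genes, 14 were called, and DESeq2 called 13 of the other 54. Over 1347 pairs of a gene and an alternative, 1220 kept direction and side of the threshold, 96 lost the call, 15 gained one and 16 changed sign, the last in 5 uncalled genes and 0 called ones. The 24 calls (3 higher, 21 lower) became 21 to 25 under the other scalings, robust = TRUE and no filter, and 27 at 1 CPM or more. Dropping the biomineral, gut and muscle members from the finished results left 18. That step only takes out the 6 called biomineral members, without a new fit, and so tests nothing further. DESeq2 gave 264 (133 higher, 131 lower; 38.5% of its calls on simulated counts were false), limma-voom 0 (0 and 0), and edgeR with legacy = TRUE 10 (1 and 9). Of the calls on simulated counts, 13.7% were false with the main edgeR fit, 4.9% with legacy = TRUE and 5.6% with limma-voom. These fits recovered 85.7%, 73.5% and 67.3% of the simulated 16-fold changes. The 24 calls may therefore hold a larger share of false ones than the false discovery threshold names. Limma-trend gave 21 (4 and 17) on log2(FPKM + 1), 31 on log2(FPKM + 0.1) (5 higher) and 1 (0 and 1) on FPKM of all genes above 0; why was not tested. Without one library the count ranged from 0 to 24, higher genes from 0 to 12 and lower genes from 0 to 21, and without ZT12 libraries 1 and 3 it was 53 (53 and 0), 1 of them shared, on the assumption that the lone ZT12 library varies like the others. Fewer samples enter these fits; beyond that the cause was not tested. With plain library sizes the median over all genes moved by 0.12, and with FPKM by 0.10 to 0.11. Over all lists 5 passed camera, 0 with an estimated correlation, 1 passed fry, 4 to 8 passed without one library (3 to 5 of the first 5), and 4 before name removals (muscle 0.0893). The lectin list, not called, was Down in fry (adjusted p = 0.972) and its adjusted p ranged from 0.522 to 0.999 without one library.

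Uncalled genes that changed sign were Cry2 (ZJQ009229), at 0.05 with plain library sizes, 0.12 with limma-voom, 0.11, 0.2 and 0.11 on the FPKM scales (pseudocounts 1, 0.1, and 1 over all genes) and -0.54 to 0.33 without one library; PHR (ZJQ014263), at -0.02 with limma-voom and -0.21 to 0.4 without one library; and, without one library, cry-dash (ZJQ000319) at -0.75 to 1.42, Cry2 (ZJQ009245) at -1.6 to 0.81 and the ferritin gene ZJQ012741 at -0.23 to 0.04. The cause was not tested.

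The replicate numbers showed no sign of pairing the libraries: same-numbered libraries had correlations of deviations of -0.05, 0.02 and 0, and no library correlated best with its own number. Taken over all genes, these correlations cannot exclude a pairing that acts on some genes only. With the number as a replicate block, edgeR called 13 genes (1 higher, 12 lower) and 8 lists passed, and Cry2 (ZJQ009229) was at 0.01. At 20229918 to 24368884 counts per library and 3 libraries per time, edgeR recovered 0% and DESeq2 6% of the 2-fold changes in the simulated comparison.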

Other observations

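The pathway test, the count of other splits for genes, that for lists with an estimated correlation, the scaling tests, the check of muscle and neural markers, the joint deviation of all 11 biomineral members and the test of genes expressed in some libraries only were chosen after the results were seen. Several genes of signalling, matrix and detoxification had large differences that did not pass edgeR over all genes. The transcription factor gene egr1 (ZJQ007433), an immediate-early gene, had 157 ± 120 CPM at ZT12 and 12.3 ± 4.08 CPM at ZT0 (SD, n = 3; edgeR adjusted p = 0.245, DESeq2 2.22e-05), with 24.2, 259 and 188 CPM in ZT12 libraries 1, 2 and 3. The fibrillar collagen gene COL2A1 (ZJQ004219) had 40.9 ± 23 and 1.14 ± 0.966 CPM (edgeR adjusted p = 0.101, DESeq2 4.71e-08). CTSC (ZJQ018929), a lysosomal peptidase gene, had 8.91 ± 3.12 and 0.789 ± 0.441 CPM (edgeR adjusted p = 0.109, DESeq2 2.67e-07). THSD7A (ZJQ002856) had 200 ± 41.2 CPM at ZT12 and 505 ± 69.3 CPM at ZT0 (edgeR adjusted p = 0.119, DESeq2 0.00016), and the abundant melanotransferrin gene MELTF (ZJQ011346) had 2350 ± 417 and 3900 ± 620 CPM (edgeR adjusted p = 0.533, DESeq2 0.16). The cytochrome P450 gene Cyp3a9 (ZJQ001908) had 56.6 ± 5.44 CPM at ZT12 and 24.8 ± 1.3 CPM at ZT0, with little spread between libraries (edgeR adjusted p = 0.117, 0.0249 adjusted over the list alone, DESeq2 1.53e-05 over all genes). The scavenger receptor gene Dmbt1 (ZJQ024964) had 56.6 ± 7.54 and 22.1 ± 11.3 CPM (edgeR adjusted p = 0.375, DESeq2 0.0526). Of the 31 tested pigment cell genes, 15 had log2 fold changes above and 16 below 0, and adjusted over the list alone 1 was higher and 2 were lower by edgeR. These were SULT1C4 (ZJQ009625, 4.27, adjusted p = 0.0267), Sult1a1 (ZJQ009291, -3.06, adjusted p = 0.0146) and the polyketide synthase gene StlB (ZJQ017623, -3.53, adjusted p = 0.0267), and the list passed fry in either direction (adjusted p = 6.69e-05). Over all genes DESeq2 called Sult1a1 (adjusted p = 0.00025) and not SULT1C4 (0.0879) or StlB (0.0759). The sensor Rigi (ZJQ020147, 2.42) and the adapter Myd88 (ZJQ002628, -2.27) had under 2 CPM at both times and did not pass.

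Of 316 pathways in the deposited annotation with 10 to 300 tested genes, 3 passed camera. Ribosome was lower (125 genes, adjusted p = 3.2e-07, 64% of them in the ribosomal protein list), and starch and sucrose metabolism (31 genes, adjusted p = 0.000938) and protein digestion and absorption (32 genes, adjusted p = 0.0287) were higher at ZT12. With an estimated correlation, and with fry, 0 pathways passed. Median and test differed in sign, or the median was 0, in 5 uncalled lists: autophagy (median -0.04, test Up), heat shock (0.05, Down), and pigment cells, Toll-like receptor signalling and xenobiotic metabolism (0). The mean went against the test in the gonad list (mean -0.32, test Up, median 0.17), and the heat shock (0.03) and antimicrobial lists (0.04), both with the test Down.

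The split by time gave 24 genes, and the highest of the other 9 ways to split the libraries 3 and 3 gave 5, so 1 of 10 splits gave as many. At an unadjusted edgeR p under 0.05 the split by time was not the highest, with 1349 genes against 1504 and 1762 in other splits. For lists, 7 of 10 splits gave at least the 5 of the split by time, and the highest other gave 17. These 10 splits are too few for a share under 0.05. The split with 17 lists set ZT12 library 1 with ZT0 libraries 1 and 3 against the rest. So many lists point to a structure of the samples other than time or to a preset correlation that is too low, and these were not separated: with an estimated correlation (0.673 for the ribosomal list in the split by time) 0 lists passed in any of the 10 splits. Such a structure was visible. ZT12 library 1 and ZT0 libraries 1 and 3 had counts for fewer genes (24007, 23487 and 23790). ZT12 libraries 2 and 3 and ZT0 library 2 had 24677, 24666 and 24656. The median ribosomal protein gene lay above its gene's mean in the former (0.05, 0.49 and 0.18 log2 units). In the latter it lay below (-0.22, -0.34 and -0.15). The cause was not tested.

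The lower biomineral genes at ZT12 are the first pattern for follow-up. Scaling by abundant genes is argued against by size, since 5 scalings differed by at most 0.12 in the median over all genes. The list's median therefore had to stay far from 0, and it lay at -3.93 or further. A candidate explanation is that skeleton-forming cells were in the ZT0 samples, and the 8 lower members deviated together from their group means, with a mean pairwise correlation of 0.29 against a median of -0.02 and a 95th percentile of 0.2 in 1000 random lists of like expression (all 11 tested members 0.25 against -0.01 and 0.13), although 3 of the 11 lay above 0, 1 of them higher adjusted over the list alone, which goes against it for these. Whole body-wall tissue would also bring muscle and nerve transcripts. In 49 such markers the median log2 fold change was 0.21 (36 above and 13 below 0), with a 95% bootstrap interval of 0.05 to 0.53. The bootstrap resampled markers and not libraries, so the interval leaves out the spread between libraries. Muscle markers separated the times, higher at ZT12. The median neural marker of ZT0 library 2 (0.23) overlapped the ZT12 libraries (0.16, 0.24 and 0.2). That library was also highest in the lower biomineral members (2.55). The markers showed no excess at ZT0 but cannot exclude such tissue. A small share could be hidden by the levels these genes have at both times. Shared regulation within coelomocytes, by time of day or otherwise, predicts the same joint deviation and stays open. With 3 libraries per time the sampling of the animals and the time are not separated. Of the 18 biomineral list members 11 were expressed enough to test. The most abundant at ZT0 were ZJQ008606 (178 CPM, chosen after its values were seen, not called, log2 fold change -1.96, edgeR adjusted p = 0.562), SM50 (97.1 CPM) and PM27 (95.1 CPM).

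The higher digestive genes at ZT12 are the next pattern. Scaling is argued against in the same way, by the small differences between the 5 scalings, and the median was 1.6 or more under each. Gut tissue, cells or contents carried over unevenly may account for it: the 40 members deviated together within a time, with a mean pairwise correlation of 0.21 against a median of 0 and a 95th percentile of 0.04 in random lists, and ZT12 library 2 (-0.25) had less than ZT0 library 3 (0.18). A feeding-related or daily programme shared by these genes in coelomocytes predicts the same and stays open. Of the 82 list members 40 were expressed enough to test; the trypsin-1 gene ZJQ009370 was abundant at both times and would hide a small carried-over share, and an alpha-amylase gene chosen after its values were seen (ZJQ004967) had 27.1 ± 28.7 CPM at ZT12 and 1.72 ± 2.98 CPM at ZT0 (SD, n = 3).

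Some genes were near absent in some libraries and expressed in others. Among all gene models 132 were under 0.1 CPM or above 1 CPM in every library, with both kinds present and at least 10 CPM in the highest, and they were on in 1, 2, 3, 4 or 5 libraries in 23, 15, 21, 29 and 44 cases. The 111 that were on in a number of libraries other than 3 cannot, by this rule, be on at one time and off at the other. Their levels can still differ by time: the libraries of CLEC6A and COL2A1 separated, while those of others overlapped. Of the 21 on in 3 libraries, 6 were on at one time and off at the other, where the highest of the other splits held 3. Time of day stays open for these genes. The 24 called genes included 2 of the 6, both on at ZT0 and without a symbol or description. These were ZJQ014675 (log2 fold change -13.23) and ZJQ021863 (-9.05), chosen after their values were seen. They had the largest absolute changes among the called genes. For these 2 calls, time of day and differences between the sampled animals are not separated. An echinoidin gene, ZJQ019150, chosen after its values were seen, had 0.04, 3199 and 0 CPM in ZT12 libraries 1, 2 and 3, and 3490, 6640 and 2870 CPM in ZT0 libraries 1, 2 and 3. A possible explanation, not tested, is that the animals differ in carrying these genes or copies the reads match, and lncRNA models made up 34.1% of them against 24.8% of all genes.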
